A study of Mus musculus with 16 samples.

How the data were processed

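Gene expression was measured by 3' end RNA sequencing in 16 libraries from 4 male C57BL/6 wildtype mice that received no treatment. Per the labels, brains were perfused and dissociated, live cells were stained, and CD11b+ microglia, EAAT2+ astrocytes and Thy1+ neurons were collected by flow cytometry with gates that left out O1+ and CD31+ cells. The remaining sample of each animal is labelled input and titled pooled, and the labels do not say at which step it was taken. It was treated as the unsorted reference of each animal. Animals 2, 3, 4 and 5 each gave 1 library per group, so that every group has 4 libraries. Libraries were made with a 3' kit that carries molecular identifiers, pooled, and read as 65 bp single ends on 1 lane, per the labels' protocols.

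The deposited counts are whole numbers per gene and library with no scaling, per the file headers. All 28936 deposited counts of 100 or more have only 2 significant digits, which allows an error of up to 5% for each. The submitters' processing notes name STAR, featureCounts, Subread 1.6.2, edgeR and the build GRCm38.p6, without saying what each did. The table holds 22058 protein-coding genes, and 21950 of their identifiers are in GENCODE M21, which gave the coordinates. The authors also deposited a library total, a scaling factor given as a ratio near 1 per library, and a normalized signal per gene whose file header calls it CPM. Their library totals are 1.06 to 1.33 times the sums of the count table, and the signal table implies library sizes somewhat above the deposited totals times the deposited factors. Signal values, totals and factors entered only alternatives.

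Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, which share 1 estimate of the spread. The fit tested 9091 genes, with a common dispersion of 0.0733. Each of the 6 pairs of groups was compared with a two-sided quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Errors written after ± are standard errors of fitted log2 fold changes, or standard deviations (SD) for CPM, with n = 4 libraries per group throughout. CPM were computed by edgeR on the TMM-scaled library size. A gene at 0 in a group was set against a floor of 3 counts over that group, and a gene with 1 to 3 counts was given as a ratio of pooled counts with an exact 95% interval. Molecular identifiers were used in the library kit, and intervals and floors cover counting error only.

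30 lists of cell type markers and pathways were fixed before the data were examined, and 4 lists (pituitary, T and NK cell, B cell, microglia-restricted response) were written afterwards. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 30 lists of a comparison, then with an estimated correlation and with fry. Each list's count of changed members was repeated with p-values adjusted over the list alone. In 38 of the 180 list tests a member had 3 or fewer counts in a group, and setting such members to their ratio or bound moved a list's median by at most 0.28 and turned no sign. Some listed genes could not be matched to the table and were not analysed here.

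The named genes follow a rule fixed before the data were examined. It takes the genes of the sort reagents (Itgam, Slc1a2, Thy1, Pecam1, Ugt8a), and per comparison the 6 largest changes in each direction among genes past the threshold with at least 50 CPM in the higher group and no overlap between the libraries of the groups. It also takes, for each list described, the 4 members with the highest mean CPM over the 16 libraries, of which the text gives 2 to 4 in that order. Predicted genes and pseudogenes were left out, and some genes that the rule names are not reported here. Genes outside the rule, such as Gh, were chosen after their values were seen.

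The animals pair the samples, since the labels give the same animals for every group. Deviations from the group means of libraries of the same animal correlated between -0.098 and 0.113 across genes, and 3 of the 24 pairs exceeded every correlation of the first library with the other animals of the second group. The model without an animal term is the one reported, and the model with animal as a block was an alternative. Other alternatives fixed beforehand were RLE scaling, no scaling beyond library totals, no filter, a test against a 2-fold change (glmTreat), fits to only the 2 groups compared, DESeq2 1.42.0, and leaving out each library. Those added after the data were seen are named with their values in the closing section. The computations were tested on simulated data made from the means and totals of these libraries, with 200 changed genes. For microglia against input, 91% of 4-fold and 36% of 2-fold changes were recovered over 8666 genes with 14 false calls, and for astrocytes against neurons 66% and 17% over 8810 genes with 3 false calls. In the data 24.9% to 53.9% of genes were called, far more than were changed here, and no sharing of transcripts was simulated. These recoveries and false calls therefore need not hold for the comparisons reported.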

Results

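The data are gene counts of 16 libraries of mouse brain cells: 4 libraries each of CD11b+ microglia, EAAT2+ astrocytes, Thy1+ neurons and input. Total counts ran from 191236 to 1413564 in microglia, from 211087 to 710828 in astrocytes, from 116761 to 393199 in neurons and from 1702665 to 2811080 in the input. The number of detected genes was 12296 ± 1423 (SD, n = 4) in microglia, 11584 ± 774.2 in astrocytes, 11640 ± 1301 in neurons and 15036 ± 163.3 in the input. Mitochondrially encoded genes held 3.77% ± 1.38 (SD, n = 4) of the counts in microglia, 9.15% ± 0.828 in astrocytes, 18.7% ± 3.19 in neurons and 8.94% ± 2.29 in the input. Within groups, log2 CPM of pairs of libraries correlated across genes between 0.772 and 0.967 in microglia, 0.747 and 0.921 in astrocytes, 0.617 and 0.802 in neurons, and 0.958 and 0.976 in the input; genes are not independent replicates. The highest correlation of any library with a library of another group was 0.747 for astrocytes and 0.73 for neurons. The lowest correlation within each of these groups was thus no higher than the highest with another group, although the 2 values need not come from the same libraries. The labels name 1 pool and 1 lane and give no batches.

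For CD11b, EAAT2 and Thy1, the antigen's own gene checks the sort. Itgam, which encodes CD11b, stood at 1726 ± 480.9 CPM (SD, n = 4) in microglia and 209.1 ± 20.81 CPM in the input. Slc1a2, which encodes the glutamate transporter EAAT2, stood at 9533 ± 851.4 CPM in astrocytes and 3221 ± 1408 CPM in the input. Thy1, which encodes a surface glycoprotein of neurons and T cells, stood at 238.5 ± 34.05 CPM in neurons and 34.65 ± 8.852 CPM in the input. The genes tied to the excluding gates were lower in all 3 sorted groups. Sorting for another cell type would lower them as well, so that these values do not test the excluding gates apart. Pecam1, which encodes CD31, stood at 25.85, 16.85 and 35.88 CPM in microglia, astrocytes and neurons against 147.5 ± 16.5 CPM in the input. Ugt8a, whose enzyme makes the galactolipid stained by O1, stood at 12.58, 32.52 and 51.45 CPM against 200.4 ± 56.56 CPM in the input. On GRCm38.p6, Itgam (ENSMUSG00000030786) lies on chromosome 7 from 128062640 to 128118491 and Slc1a2 (ENSMUSG00000005089) on chromosome 2 from 102658659 to 102790784. Thy1 (ENSMUSG00000032011) lies on chromosome 9 from 44043384 to 44048579, Pecam1 (ENSMUSG00000020717) on chromosome 11 from 106654217 to 106750628, and Ugt8a (ENSMUSG00000032854) on chromosome 3 from 125865271 to 125938619.

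**Figure D1:**
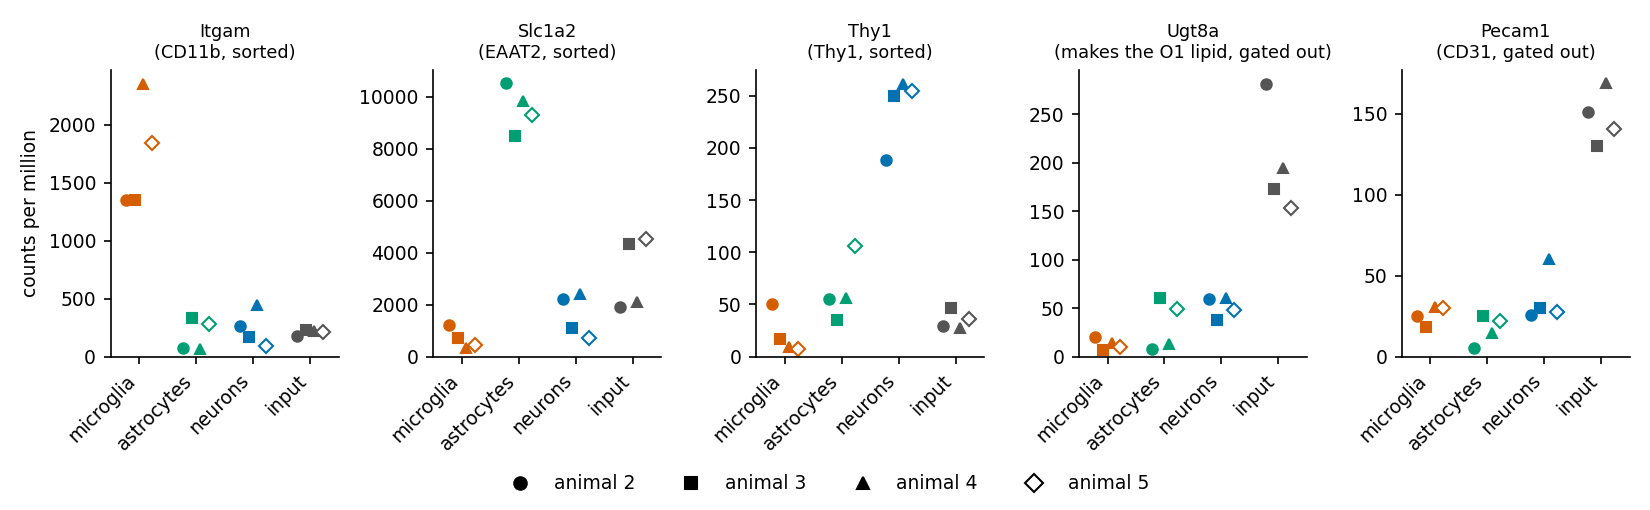
CPM (vertical axis, linear from 0) of the genes behind the sorting reagents in each library, by group (horizontal axis, color) and animal (symbol). Itgam averaged 1726 CPM in microglia, Slc1a2 9533 CPM in astrocytes and Thy1 238.5 CPM in neurons, while Ugt8a and Pecam1 averaged 200.4 and 147.5 CPM in the input.

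Counts of transcripts of the other cell types were present in every sorted group. The sums below do not separate cells of another type from transcripts shared between the pooled libraries. The microglia list summed to 66372 ± 13370 CPM (SD, n = 4) in microglia, 6936 ± 3997 in astrocytes, 8286 ± 4861 in neurons and 12398 ± 825.3 in the input. The astrocyte list summed to 47634 ± 9115 CPM in astrocytes, 3212 ± 1876 in microglia, 7122 ± 3300 in neurons and 12976 ± 3831 in the input. The neuron list summed to 4885 ± 1391 CPM in neurons, 404.4 ± 169.1 in microglia, 1010 ± 258.6 in astrocytes and 1760 ± 317.4 in the input. Astrocyte libraries differed among themselves: microglia transcripts summed to 10361 and 10431 CPM in astrocytes 3 and 5, the shallower libraries, and to 3371 and 3580 CPM in astrocytes 2 and 4. An estimate of shared transcripts, described in the closing section, took 46.2% and 40.1% of the counts of astrocytes 3 and 5. It took 12.4% and 14.7% of those of astrocytes 2 and 4. Lymphocyte transcripts summed to 387.1 ± 118 CPM in neurons and to 30.75 ± 10.64, 37.5 ± 32.03 and 23.09 ± 8.998 CPM in microglia, astrocytes and input.

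**Figure D2:**
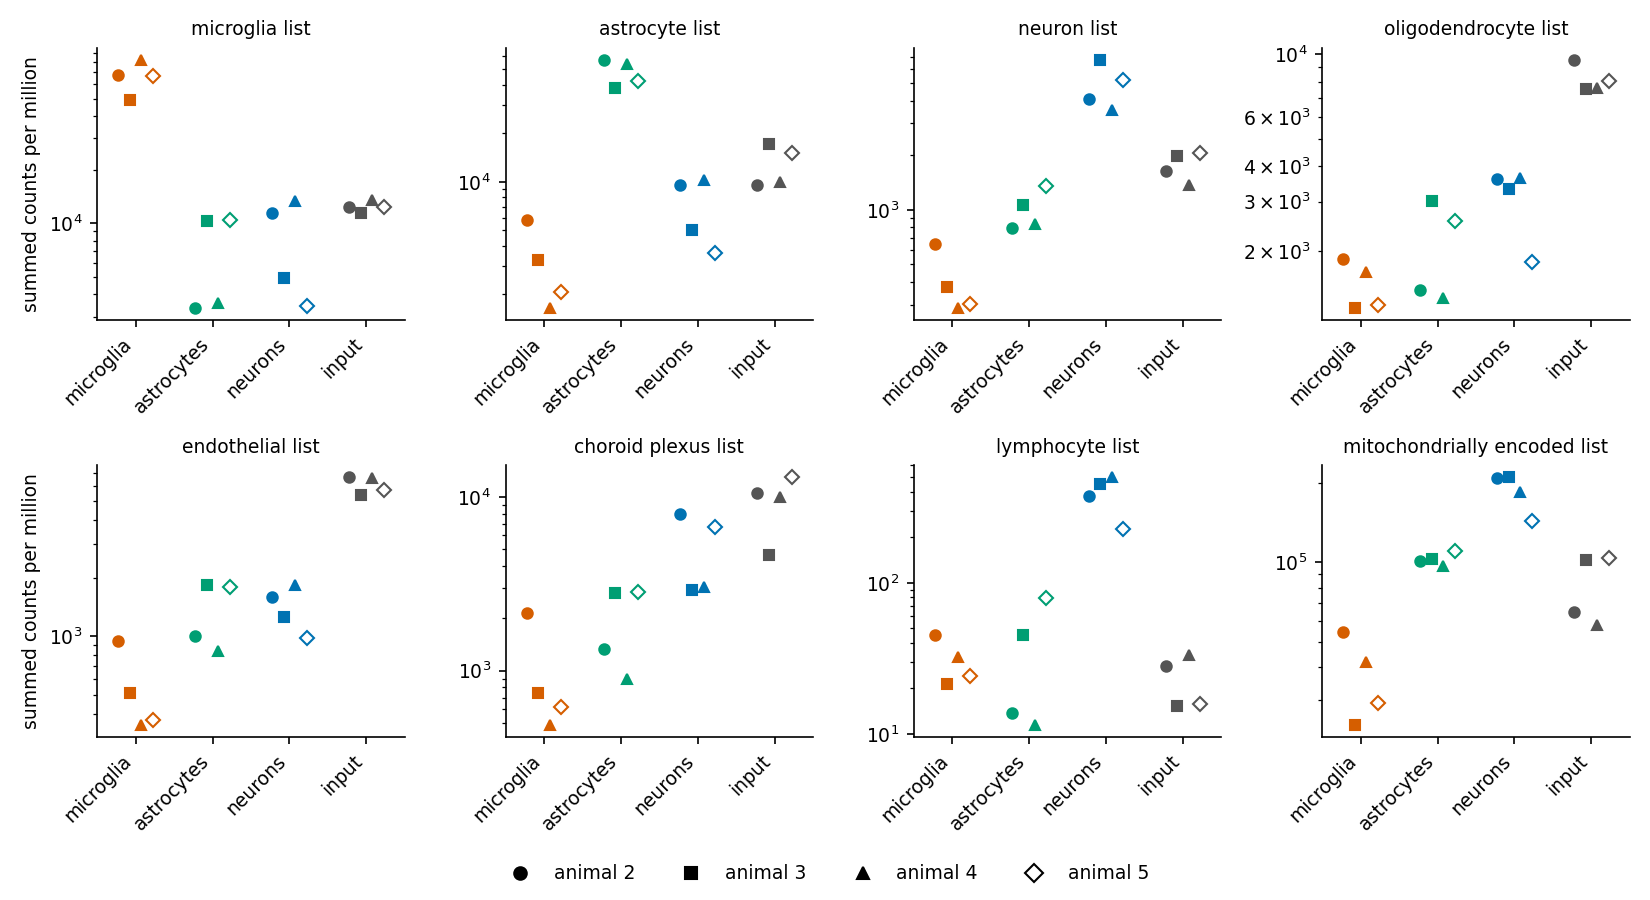
Summed CPM (vertical axis, log scale) of the members of 8 gene lists in each library, by group (horizontal axis, color) and animal (symbol). The microglia, astrocyte and neuron lists averaged 66372, 47634 and 4885 CPM in their own groups, and the lymphocyte list averaged 387.1 CPM in neurons.

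Transcripts of pituitary hormones were found in every library. Gh, which encodes growth hormone, had 110 to 250 counts in each of the 12 libraries of animals 2, 3 and 4, whose totals differed 24.1-fold. In animal 5, Gh had 19000 counts in neurons (65320 CPM), 5600 in the input (2313 CPM), 530 in microglia and 250 in astrocytes.

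**Figure D3:**
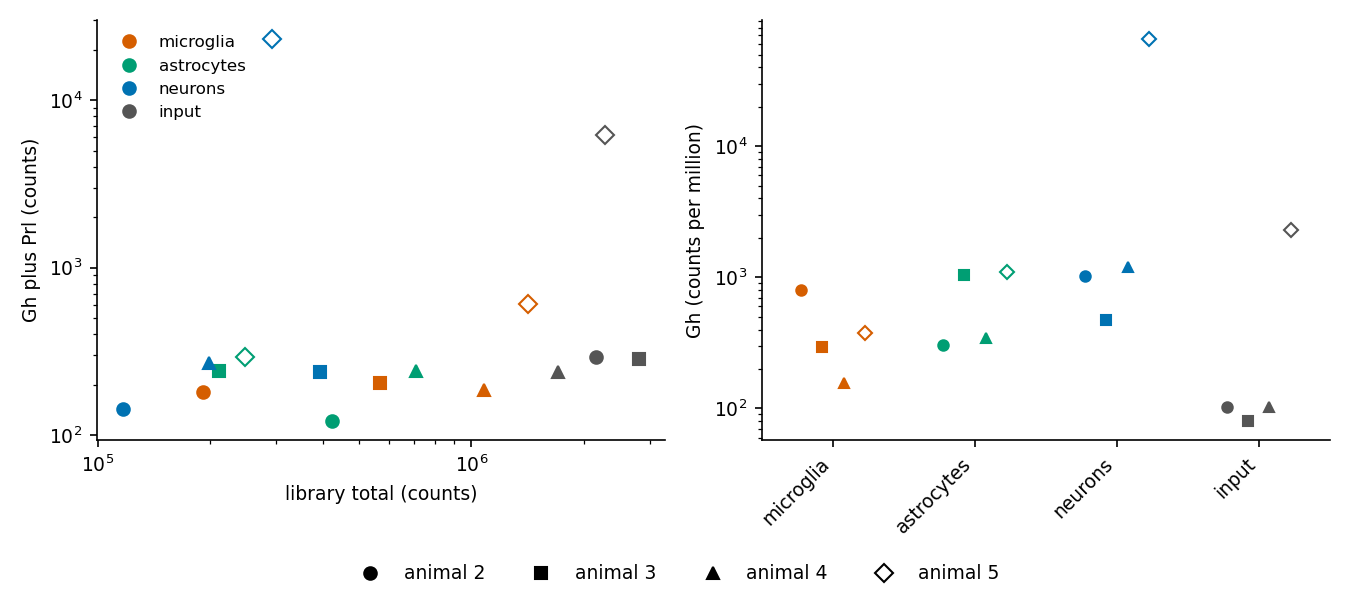
Left, counts of Gh plus Prl against the library total, both on log axes; right, Gh CPM on a log axis by group. Points are single libraries, with color for the group and symbol for the animal. Gh plus Prl had 121 to 293 counts in the libraries of animals 2, 3 and 4, while neurons 5 reached 65320 CPM of Gh.

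Microglia against input asked which transcripts the CD11b gate enriched. Cx3cr1, the fractalkine receptor, rose by a log2 fold change of 1.97 ± 0.40, Ctss, a lysosomal protease, by 2.63 ± 0.43, and C1qc, a chain of complement C1q, by 2.86 ± 0.40. Itgam rose by 3.05 ± 0.41. Of the genes induced early by cell stimulation and stress, Zfp36 stood at 4.02 ± 0.41, Rhob at 2.46 ± 0.28, Junb at 3.61 ± 0.36 and Jun at 3.20 ± 0.32. The largest increases with no overlap between libraries were those of Clec2d (4.80 ± 0.56), Hnrnpa1 (4.62 ± 0.42), the chemokines Ccl3 (4.62 ± 0.41) and Ccl4 (4.17 ± 0.40), Csf3r (4.19 ± 0.46) and Pou2f2 (4.06 ± 0.32). Among the largest decreases, Vtn, which is strong in pericytes, stood at -4.99 ± 0.40, Car4 at -5.05 ± 0.50, Myl9 at -5.09 ± 0.55 and Ccdc153 at -5.43 ± 0.54. Fstl1 and Kcna1 had 3 counts each in microglia and were 62.5-fold (95% interval 21.3 to 304) and 54.6-fold (18.6 to 266) lower. Slc1a2 fell to -2.27 ± 0.40, Pecam1 to -2.47 ± 0.31 and Ugt8a to -4.13 ± 0.41. Thy1 fell by 1.30 with an adjusted p of 0.009, a call that ended without microglia 4 (-0.85) or microglia 5 (-0.88), without animal 5 (-0.88), with DESeq2 (-1.04) and with every library thinned to the smallest total (-0.55).

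By list, all 20 microglia genes rose (20 adjusted over the list alone), with adjusted p = 0.175 with an estimated correlation. Complement genes rose in 8 of 8 (8 adjusted over the list alone), with adjusted p = 0.175 with an estimated correlation. Early response and stress genes rose in 16 of 18 (16 adjusted over the list alone; adjusted p = 0.0766 with an estimated correlation). Border macrophage genes rose in 7 of 7 (7 adjusted over the list alone), among them Mrc1 at 2.13 ± 0.28 and F13a1 at 2.21 ± 0.35 (adjusted p = 0.127 with an estimated correlation). Monocyte and neutrophil genes rose in 8 of 9 (9 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), among them S100a9 at 3.17 ± 0.52, which was 2.52 without microglia 4, and S100a8 at 1.84 ± 0.44. MHC class II genes rose in 6 of 6 (6 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), with H2-Aa at 1.59 ± 0.37 and H2-Ab1 at 1.68 ± 0.31. Lysosome genes rose in 19 of 28 (19 adjusted over the list alone), with adjusted p = 0.11 with an estimated correlation. Astrocyte genes fell in 21 of 21 (21 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation) and neuron genes in 18 of 19 (18 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with Map2 at -3.18 ± 0.32 and Syt1 at -2.85 ± 0.42. Oligodendrocyte genes fell in 15 of 16 (15 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with Mbp at -2.60 ± 0.34, and Trf stayed at -0.10 ± 0.28. Endothelial genes fell in 15 of 15 (15 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), with Flt1 at -4.00 ± 0.41. Choroid plexus genes fell in 9 of 9 (9 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), with Ttr, the thyroid hormone carrier, at -3.20 ± 0.48. Hemoglobin and other erythroid genes fell in 5 of 5 (5 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 8 (7 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation), and their list was called with the preset correlation only without input 4. Of these, mt-Nd4 at -1.07 ± 0.35 and mt-Nd1 at -1.08 ± 0.35 lost their calls without animal 5 (-0.87 for both).

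In all, 4902 of 9091 genes differed between microglia and input, 2192 higher and 2710 lower in microglia. Without microglia 4, 2294 were higher and 2218 lower, and without microglia 2, 2818 and 2862. Of the 26 lists called with the preset correlation none held with an estimated one, and fry called 27. The libraries of the groups did not overlap for 4763 genes, or 52.4% against 2.86% by chance. When an estimate of transcripts shared between libraries was subtracted, 3255 genes differed, the share higher in microglia went from 44.7% to 24.3%, and the calls of Ctss (2.55), H2-Aa (1.40) and H2-Ab1 (1.44) ended.

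Astrocytes against input asked what the EAAT2 gate enriched. Slc1a2 rose by 1.56 ± 0.39, Aldoc, a glycolytic enzyme strong in astrocytes, by 2.12 ± 0.40, and Slc1a3, the other main glial glutamate transporter, by 2.15 ± 0.38. Of the genes of cholesterol synthesis, Msmo1 stood at 2.39 ± 0.29 and Hmgcs1 at 1.00 ± 0.27. The calls of Slc1a2 (1.64) and Hmgcs1 (0.98) ended with the estimate of shared transcripts subtracted, although the fitted change of Slc1a2 grew and that of Hmgcs1 hardly moved. The largest increases with no overlap between libraries were those of Tubb2b (5.14 ± 0.38), Rgs20 (4.75 ± 0.36), the ciliary neurotrophic factor receptor Cntfr (4.70 ± 0.40), Nyap1 (4.55 ± 0.54), Lars2 (4.45 ± 0.43) and Ggt7 (4.27 ± 0.55). The largest decreases were those of Cdh5, the endothelial cadherin, at -4.75 ± 0.54, Ccdc153 at -4.59 ± 0.58, the oligodendrocyte factor Sox10 at -4.49 ± 0.66 (-5.22 without astrocytes 5), Nov at -4.13 ± 0.47 and Cdkn1c at -4.11 ± 0.50. F5 had 3 counts in astrocytes and was 26.7-fold lower (95% interval 9.08 to 130). Pecam1 was lower at -3.25 ± 0.37 and Ugt8a at -2.87 ± 0.40, while Thy1 at 0.84 ± 0.37 (adjusted p 0.075) and Itgam at -0.23 ± 0.41 (0.696) passed no threshold. Thy1 was called with only these 2 groups in the fit (0.94) and without astrocytes 3 (0.98), and Itgam with the estimate of shared transcripts subtracted (-5.19).

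By list, astrocyte genes rose in 19 of 21 (20 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). Glutamate and potassium clearance genes rose in 8 of 8 (8 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), and cholesterol synthesis genes in 13 of 13 (13 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). Endothelial genes fell in 15 of 15 (15 adjusted over the list alone; adjusted p = 0.0959 with an estimated correlation), with Flt1 at -2.59 ± 0.38. Slc2a1, the glucose transporter of this list, fell by 0.80, a call that ended with RLE scaling (-0.70), with DESeq2 (-0.71), with the subtraction (-1.46), without animal 5 (-0.82) and without any of astrocytes 3, 4 or 5 or input 2, 3 or 4 (from -0.60 to -0.84). Oligodendrocyte genes fell in 14 of 16 (15 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), with Mbp at -2.07 ± 0.34 and Trf at -1.67 ± 0.30. Choroid plexus genes fell in 9 of 9 (9 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation), with Ttr at -2.23 ± 0.46 and Prlr at -3.41 ± 0.46. Neuron genes fell in 12 of 19 (12 adjusted over the list alone; adjusted p = 0.421 with an estimated correlation), with Syt1 at -1.90 ± 0.40, and Map2 stayed at 0.03 ± 0.27. Microglia genes fell in 10 of 20 (11 adjusted over the list alone; adjusted p = 0.459 with an estimated correlation), with Cx3cr1 at -1.29 ± 0.40, a call that ended without astrocytes 2 (-1.01) or astrocytes 4 (-0.96), and Ctss at -0.46 ± 0.41 (adjusted p 0.398), which was called with the subtraction (-5.39). Of 5 oligodendrocyte precursor genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.635 with an estimated correlation), with Olig2 at 1.51 ± 0.33 and Olig1 at 0.66 ± 0.30 (adjusted p 0.0799), the latter called with only these 2 groups fitted (0.78).

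In all, 3214 of 9091 genes differed between astrocytes and input, 1480 higher and 1734 lower in astrocytes. Of the 18 lists called with the preset correlation none held with an estimated one, and fry called 23. Groups did not overlap for 3439 genes, or 37.8% against 2.86% by chance. Without astrocytes 4, 1335 were higher and 961 lower, or 58.1% higher against 46.0% with all libraries. The share higher was 52.8% with RLE, 51.6% with DESeq2, 27.2% with library totals only and 25.3% with the estimate of shared transcripts subtracted.

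Neurons against input asked what the Thy1 gate enriched. Snap25, a protein of synaptic vesicle fusion, rose by 1.79 ± 0.34, the neuronal RNA-binding protein gene Celf4 by 2.23 ± 0.28, and Slc17a7, the vesicular glutamate transporter of cortical neurons, by 3.56 ± 0.33. Thy1 rose by 2.79 ± 0.35. The 6 largest increases with no overlap between libraries were all in genes known from lymphocytes, with Cd27 at 6.90 ± 0.68, Lat at 6.48 ± 0.61, Tnfrsf18 at 6.22 ± 0.56, Ms4a4b at 6.08 ± 0.46, Ltb at 6.01 ± 0.58 and Cd8a at 5.85 ± 0.62 (6.44 without input 2). The largest decreases were those of the hemoglobin gene Hba-a2 at -3.35 ± 0.47, Cp at -3.27 ± 0.59, Clic6 of the choroid plexus at -3.21 ± 0.45, Wwtr1 at -3.19 ± 0.47 and Car14 at -3.13 ± 0.56 (-3.84 without neurons 4). Edn1 had 3 counts in neurons and was 17.1-fold lower (95% interval 5.8 to 83). Pecam1 was lower at -2.05 ± 0.34 and Ugt8a at -2.02 ± 0.38, while Itgam stood at 0.18 ± 0.41 (adjusted p 0.781) and Slc1a2 at -1.0 ± 0.39 (0.0574). Slc1a2 was called lower with library totals only (-1.12), with no filter (-1.08), with the effective sizes of the deposited table (-1.13), without neurons 2 (-1.20), neurons 4 (-1.29), input 2 (-1.21) or input 4 (-1.18), and with the estimate of shared transcripts subtracted (-3.27), which also turned Itgam to -2.36.

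By list, neuron genes rose in 17 of 19 (17 adjusted over the list alone; adjusted p = 0.0671 with an estimated correlation), and Map2 stood at 0.27 ± 0.27. Syt1 rose by 1.27 ± 0.35, a call that ended without neurons 3 (1.05). Excitatory neuron genes rose in 7 of 8 (8 adjusted over the list alone; adjusted p = 0.0477 with an estimated correlation), with Nrgn at 1.51 ± 0.31 and Camk2a at 1.38 ± 0.34, the latter not called without neurons 3 (1.05). Synaptic vesicle genes rose in 13 of 17 (14 adjusted over the list alone; adjusted p = 0.0477 with an estimated correlation). Of 5 genes of striatal projection neurons, 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0671 with an estimated correlation), with the enkephalin gene Penk at 2.52 ± 0.37 and Ppp1r1b, which encodes DARPP-32, at -1.23 ± 0.33. Lymphocyte genes rose in 4 of 4 (4 adjusted over the list alone; adjusted p = 0.000881 with an estimated correlation), with the T cell kinase gene Lck at 5.29 ± 0.46, Cd3d at 5.30 ± 0.56 and Nkg7 of cytotoxic cells at 5.25 ± 0.52. Of the list's 11 matched members, only these 4 passed the filter on low counts. The list's sum was low in the other groups, so that members passed mainly by being high in neurons, which favoured this result. Its 4 B cell members were not tested and had 13 counts in neurons and 130 in the input (log2 ratio of summed CPM -0.05). Mitochondrially encoded genes rose in 7 of 8 (7 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), with mt-Nd1 at 1.29 ± 0.36 and mt-Nd4 at 1.18 ± 0.35, the latter not called without input 2 (1.09) or input 4 (1.01). Mural cell genes fell in 9 of 10 (9 adjusted over the list alone; adjusted p = 0.0477 with an estimated correlation), with Rgs5 at -1.71 ± 0.33 and Acta2 at -1.91 ± 0.33. Endothelial genes fell in 15 of 15 (15 adjusted over the list alone; adjusted p = 0.0671 with an estimated correlation), and oligodendrocyte genes in 15 of 16 (16 adjusted over the list alone; adjusted p = 0.0741 with an estimated correlation), with Trf at -1.90 ± 0.31, while Mbp stood at -0.67 ± 0.32 (adjusted p 0.117). Among markers of the other sorted types, microglia genes fell in 5 of 20 (6 adjusted over the list alone; adjusted p = 0.535 with an estimated correlation) and astrocyte genes in 7 of 21 (8 adjusted over the list alone; adjusted p = 0.495 with an estimated correlation). The preset call of the microglia list ended without neurons 5 (median -0.41) and without animal 5 (-0.39). With the estimate of shared transcripts subtracted, Cx3cr1 (-14.40), C1qc (-12.05), Ctss (-4.61), Aldoc (-2.95), Slc1a3 (-2.67) and Mlc1 (-2.37) were called lower.

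In all, 2264 of 9091 genes differed between neurons and input, 1020 higher and 1244 lower in neurons, and 1417 differed without the libraries of animal 5. Of the 20 lists called with the preset correlation 4 held with an estimated one, and fry called 21. Groups did not overlap for 2596 genes, or 28.6% against 2.86% by chance. Without neurons 3, 751 genes were higher and 799 lower. The share higher in neurons was 45.1%, and it was 58.5% with RLE, 34.9% with library totals only, 57.8% with only these 2 groups fitted, 64.1% with DESeq2, which has its own filter and test, and 21.3% with the estimate of shared transcripts subtracted, which ended the calls of Syt1 (1.44), Camk2a (1.51), mt-Nd4 (1.30) and mt-Nd1 (1.45). The fitted changes of these genes grew with the subtraction, so that their calls did not end through a smaller change.

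**Figure D4:**
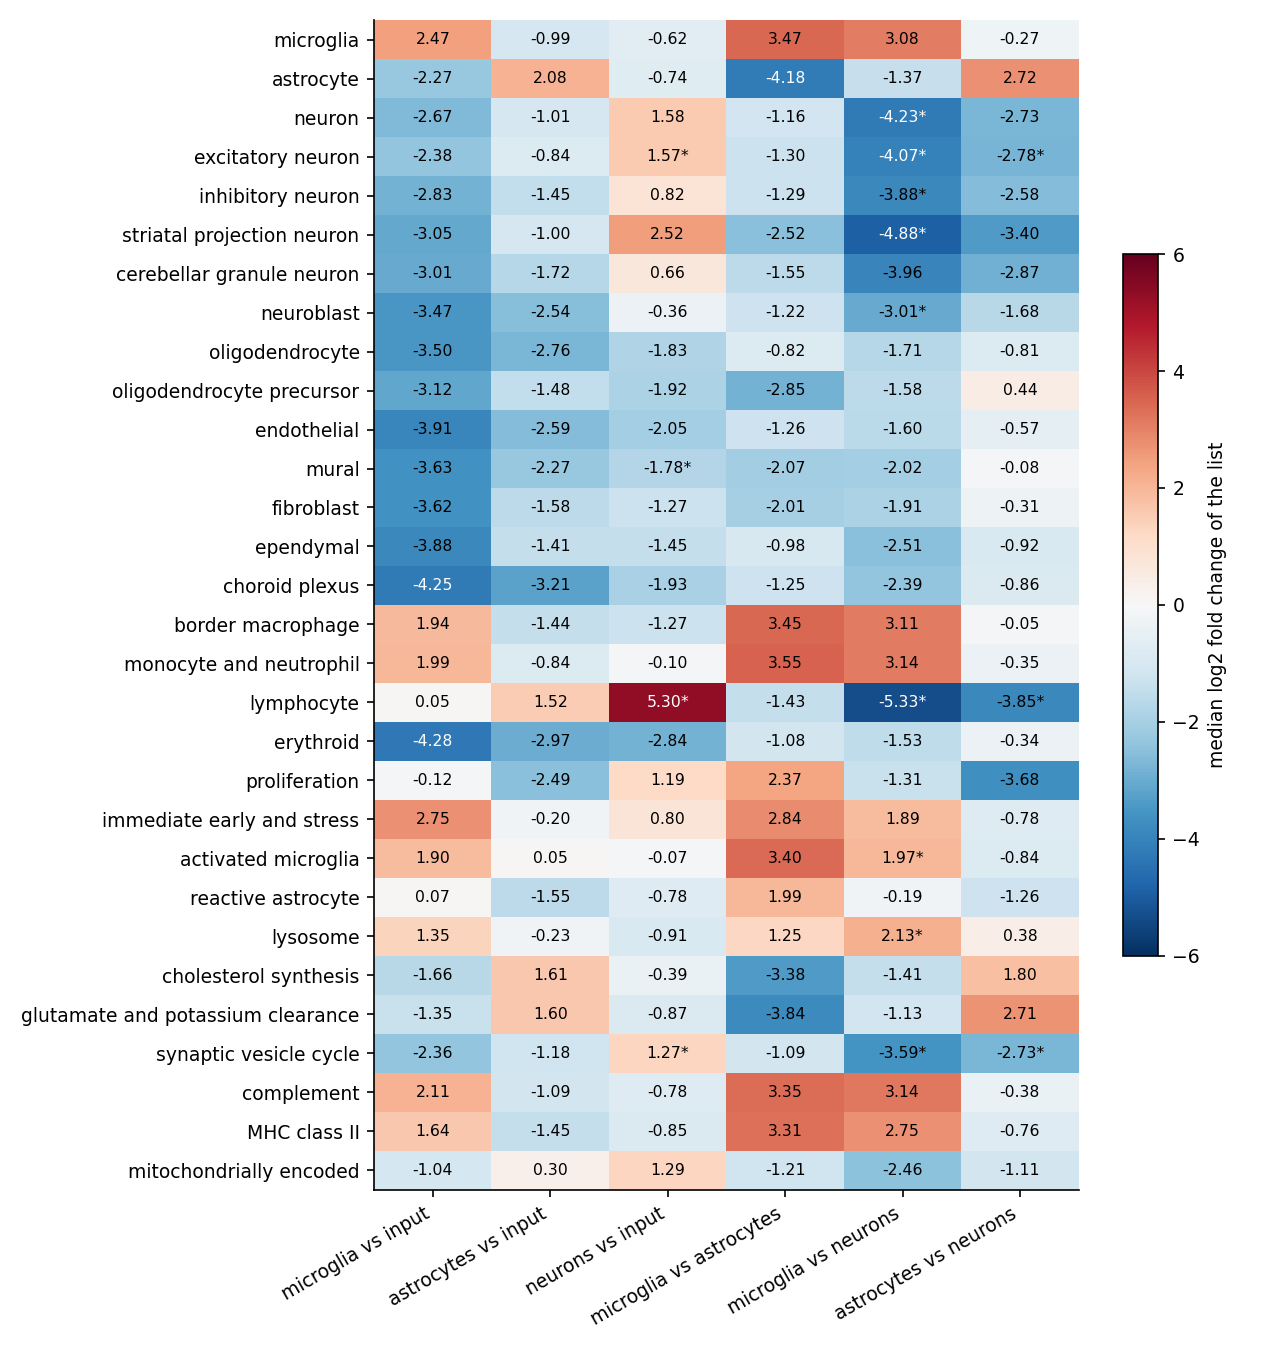
Median log2 fold change (color and printed value, first group minus second) of the tested members of each of the 30 lists in the 6 comparisons. A star marks lists with an adjusted p under 0.05 with an estimated correlation. The tested lymphocyte genes, which passed the filter on low counts mainly by being high in neurons, had a median of 5.30 in neurons against input.

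Microglia against astrocytes compared both glial sorts directly. Cx3cr1 was higher in microglia at 3.27 ± 0.42 and Ctss at 3.09 ± 0.44, while Slc1a2 was lower at -3.83 ± 0.43 and Aldoc at -4.18 ± 0.44. Itgam rose by 3.28 ± 0.43 and Thy1 fell by 2.13, which was -1.43 without animal 5 and not called in thinned libraries (-1.17). Among the largest increases, Stab1, a scavenger receptor of macrophages, rose by 5.30 ± 0.51 (7.32 without astrocytes 4), and Tlr12 and Cd300a had 2 counts each in astrocytes and were 73.7-fold (95% interval 20.2 to 611) and 54-fold (14.8 to 449) higher. Plac8 (2 counts), Socs3 (3) and Tfpi (3) were 46.5-fold (12.7 to 386), 39.6-fold (13.4 to 193) and 37-fold (12.5 to 181) higher. The largest decreases were those of Tst at -6.12 ± 0.61 (-6.81 without microglia 4), Ppp1r3g at -5.95 ± 0.68 (-6.57 without microglia 3), Fam69c at -5.79 ± 0.66 (-6.73 without microglia 2), the mitochondrial carrier gene Slc25a18 at -5.73 ± 0.42 and the metallothionein gene Mt3 at -5.70 ± 0.42. Fstl1 had 3 counts in microglia and was 71-fold lower (23.5 to 350). Ugt8a fell by 1.26 with an adjusted p of 0.0394, a call that ended with animal as a block (-1.25), with library totals only (-1.10), in thinned libraries (-1.67), without animal 5 (-0.83) and without any of microglia 3, 4 or 5 or astrocytes 3 or 5 (from -0.75 to -1.36), and turned to 2.35 with the subtraction.

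By list, microglia genes rose in 20 of 20 (20 adjusted over the list alone) and astrocyte genes fell in 21 of 21 (21 adjusted over the list alone), each with adjusted p = 0.154 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 13 (13 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), with Msmo1 at -3.42 ± 0.31 and Hmgcs1 at -2.90 ± 0.29. Early response and stress genes rose in 17 of 18 (17 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), with Zfp36 at 3.63 ± 0.41 and Rhob at 2.06 ± 0.28. MHC class II genes rose in 6 of 6 (6 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), with H2-Aa at 3.00 ± 0.46 and H2-Ab1 at 3.79 ± 0.42. Oligodendrocyte precursor genes fell in 3 of 5 (3 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), with Olig1 at -3.78 ± 0.37 and Olig2 at -3.77 ± 0.42, and the list's preset call ended without microglia 3 (median -2.49), microglia 5 (-2.35), astrocytes 3 (-1.59), astrocytes 5 (-2.03) or animal 5 (-2.60). In all, 4531 of 9091 genes differed, 2160 higher and 2371 lower in microglia, against 2535 higher and 2063 lower with library totals only. Of the 15 lists called with the preset correlation none held with an estimated one, and fry called 28. Groups did not overlap for 3386 genes, or 37.2% against 2.86% by chance.

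Microglia against neurons compared the CD11b and Thy1 gates. Snap25 was lower in microglia at -4.34 ± 0.41, Syt1 at -4.13 ± 0.43 and Slc17a7 at -5.38 ± 0.42, while Cx3cr1 was higher by 2.99 ± 0.42 and Ctss by 2.83 ± 0.43. With the estimate of shared transcripts subtracted, Snap25 went to -6.50, Syt1 to -6.91, Slc17a7 to -7.38, Cx3cr1 to 16.23 and Ctss to 7.15. The directions held, but the sizes depend on whether shared transcripts are removed. Itgam rose by 2.86 ± 0.43 and Thy1 fell by 4.08. The largest increases included Naip5 at 4.69 ± 0.64 (5.37 without neurons 4), the lipopolysaccharide receptor gene Cd14 at 4.52 ± 0.50, Tlr13 at 4.44 ± 0.53 and Kcnk6 at 4.43 ± 0.45, with Pik3r6 and Cysltr1 at 3 counts in neurons and 28.2-fold (95% interval 9.55 to 138) and 25.1-fold (8.49 to 123) higher. Among the largest decreases were St8sia3 at -6.14 ± 0.56, Sult4a1 at -6.02 ± 0.59 and Nkg7 at -5.85 ± 0.67 (-6.49 without microglia 3), with the dopamine receptor gene Drd1 (2 counts in microglia) and Cd27 (3) at 69.1-fold (18 to 589) and 71.8-fold (23.5 to 357) lower. Cd27 and Nkg7 were among the lymphocyte genes that were higher in neurons than in the input. Prl, which encodes prolactin, had the largest decrease at -6.17 ± 1.19, and the size of this change rested on neurons 5. Prl was -1.58 and not called without that library. It was still called without animal 5 (-1.64) and with animal as a block (-3.65). In animals 2, 3 and 4, however, Prl had 22, 24 and 25 counts in microglia and 23, 48 and 31 in neurons. The neurons library of each of these animals had the lower total. The change of -1.64 can therefore not be told apart from a background that does not follow depth, as described for Gh plus Prl in the closing section.

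By list, neuron genes fell in 19 of 19 (19 adjusted over the list alone; adjusted p = 0.0429 with an estimated correlation). Synaptic vesicle genes fell in 17 of 17 (17 adjusted over the list alone; adjusted p = 0.0429 with an estimated correlation). Lymphocyte genes fell in 4 of 4 (4 adjusted over the list alone; adjusted p = 0.0429 with an estimated correlation), with Lck at -5.79 ± 0.58. These members passed the filter on low counts mainly by being high in neurons, which favoured this result. Lysosome genes rose in 26 of 28 (26 adjusted over the list alone; adjusted p = 0.0429 with an estimated correlation), with Ctss among them. Microglia genes rose in 20 of 20 (20 adjusted over the list alone; adjusted p = 0.0718 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 8 (8 adjusted over the list alone; adjusted p = 0.0985 with an estimated correlation), with mt-Nd4 at -2.25 ± 0.36 and mt-Nd1 at -2.38 ± 0.37. In all, 4054 of 9091 genes differed, 1837 higher and 2217 lower in microglia, and 2387 differed when only these 2 groups were fitted. Of the 24 lists called with the preset correlation 9 held with an estimated one, and fry called 28. Subtraction of the estimate of shared transcripts ended the preset calls of the astrocyte (median -1.71), oligodendrocyte (-1.84), endothelial (0), mural (-2.22), choroid plexus (-5.93) and cholesterol synthesis lists (-1.94). Groups did not overlap for 2801 genes, or 30.8% against 2.86% by chance.

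Astrocytes against neurons compared the EAAT2 and Thy1 gates. Slc1a2 was higher in astrocytes by 2.57 ± 0.41, Aldoc by 2.82 ± 0.41 and Glul, which encodes glutamine synthetase, by 2.36 ± 0.34, while Syt1 was lower at -3.17 ± 0.41, Celf4 at -3.56 ± 0.33 and Thy1 at -1.95 ± 0.37. The largest increases included Gdpd2 at 4.67 ± 0.64, Slc27a1 at 4.18 ± 0.49, Gpld1 at 4.11 ± 0.46 (4.70 without neurons 5) and Tst at 4.47 ± 0.64 (3.79 without neurons 3, 5.27 without neurons 5), with Nr2e1 and Kirrel2 at 3 counts in neurons and 26.4-fold (95% interval 8.8 to 130) and 21.4-fold (7.08 to 106) higher. Ltb, 1 of the lymphocyte genes that were higher in neurons than in the input, had no counts in astrocytes. It was lower there by 35.2-fold against a floor of 3 counts over the group, and by at least 27.9-fold at the limit of the exact 95% interval of its counts. Other large decreases were those of Eef1a2 at -4.91 ± 0.58, Cxcr6 at -4.86 ± 0.51 and H2-Q7 at -4.88 ± 0.61 (-4.17 without astrocytes 4, -5.90 without astrocytes 3), with Klrd1 (2 counts in astrocytes) and Rnf112 (3) at 50.7-fold (13.5 to 426) and 46.3-fold (15.4 to 228) lower.

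By list, astrocyte genes rose in 21 of 21 (21 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), glutamate and potassium clearance genes in 8 of 8 (8 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation) and cholesterol synthesis genes in 11 of 13 (11 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation). Excitatory neuron genes fell in 8 of 8 (8 adjusted over the list alone), synaptic vesicle genes in 16 of 17 (16 adjusted over the list alone) and lymphocyte genes in 4 of 4 (4 adjusted over the list alone), each with adjusted p = 0.0485 with an estimated correlation. The lymphocyte members passed the filter on low counts mainly by being high in neurons, which favoured their result. Neuron genes fell in 18 of 19 (18 adjusted over the list alone; adjusted p = 0.0583 with an estimated correlation). Microglia genes, foreign to both gates, were lower in 1 of 20 (0 adjusted over the list alone; adjusted p = 0.83 with an estimated correlation), and their preset call, absent in the full data, appeared without neurons 5 (median -0.53) and without animal 5 (-0.80). In all, 2590 of 9091 genes differed, 1343 higher and 1247 lower in astrocytes, and 1392 differed when only these 2 groups were fitted. Of the 15 lists called with the preset correlation 3 held with an estimated one, and fry called 17. Groups did not overlap for 1813 genes, or 19.9% against 2.86% by chance.

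Median, mean and test differed in sign for a few lists, none of which was called by camera with the preset correlation. Against the input, these were the proliferation list (median -0.12, mean -0.12) and the reactive astrocyte list (0.07, -0.11) in microglia, the activated microglia list (0.05, -0.64) in astrocytes and the monocyte and neutrophil list (-0.10, 0.03) in neurons. Between sorted groups, these were the reactive astrocyte list for microglia against neurons (-0.19, 0.52), and the mural (-0.08, 0.06) and activated microglia lists (-0.84, -0.58) for astrocytes against neurons.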

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

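Tests of the pituitary transcripts, of the T and NK cell transcripts and of the response genes were chosen after those results were seen, as were the genes and lists searched for outlying libraries. The slopes of genes counted mainly in the input and of each population's own markers, and the splits of the libraries, were planned before their results.

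In each group of 4 libraries, a library was singled out when its gap to the nearest other, as a part of the group's range, passed Dixon's 95% critical value. Chance marks about 1 in 20 groups, and 10 of the 88 groups searched had such a library. Gh stood at 65320 CPM in neurons 5 and at 2313 CPM in input 5, and Prl at 14090 and 252 CPM in the same libraries. In microglia 4, S100a8 stood at 4124 CPM, S100a9 at 5598 CPM and the monocyte and neutrophil list at a sum of 12692 CPM. The choroid plexus list summed to 2154 CPM in microglia 2, Thy1 stood at 187.9 CPM in neurons 2, below the other neurons libraries, and Pecam1 at 60.37 CPM in neurons 4. Several of these are the same signal counted more than once, since Gh and Prl come from 1 tissue and S100a8 and S100a9 belong to the monocyte and neutrophil list.

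Pituitary transcripts formed the first pattern. In animals 2 to 4, Gh plus Prl counts barely followed the library total (slope 0.10, 95% interval -0.27 to 0.47; from -0.01 to 0.21 without each library), which is consistent with transcripts shared between libraries of the pool, and the upper bound of 0.47 argues against pituitary RNA in proportion to each library. Genes counted mainly in the input had a median slope of 0.41 over the sorted libraries (0.33 to 0.44 without each library), while each population's own markers had 1.24, just inside the bound set for it, and outside it in astrocytes and neurons taken alone, with 1.04 in microglia, 1.28 in astrocytes and 1.62 in neurons. For animal 5, neurons 5 held 68.7% of the pooled Gh count, more than sharing would give. The pituitary list was written after such genes were seen to be high there, so that it adds no independent support for pituitary tissue in that suspension, which stays open: all 12 listed genes were highest in the neurons or input library of animal 5. The median of 4.56 in neurons against input moved with the libraries of animal 5, being 0.72 without neurons 5, 6.62 without input 5 and 3.05 without animal 5. Without animal 5, 3 of the 4 tested genes were still called higher in neurons. In animals 2, 3 and 4, Gh had 120, 190 and 240 counts in neurons and 250, 240 and 200 in the deeper input libraries. For Gh, a rise without animal 5 can therefore not be told apart from depth. A fixed amount of background RNA per tube would also give counts that do not follow depth, and it was not tested apart from sharing.

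T and NK cell transcripts in the neurons libraries formed the second pattern. The T and NK cell list, 7 of whose 14 genes are also in the lymphocyte list, was written after such genes were seen to be high there, so that its median of 5.30 repeats that observation. Its share of pooled counts in the neurons libraries, 66.5% (1107 of 1664), was favoured by that choice as well. Of the lymphocyte list, which was fixed beforehand, these libraries held 52.9% (388 of 734; at least 37.7% without 1 of them) against 6.76% of all counts, which argues against transcripts shared between libraries. Blood cells of every kind were tested through erythroid genes alone. Their median of -2.84 argues against red cells and does not cover other blood cells. The T and NK cell median lay 6.37 above that of the B cell list, a difference that the choice of genes favoured, and the B cell list had 1 tested gene, Blnk (-1.08), which microglia also express; summed CPM gave a difference of 5.80, or 5.49 without Blnk. Divided afterwards by cell type, the 7 T and NK cell genes of the lymphocyte list had 70.1% of their counts in neurons and its 4 B cell genes 6.53% (13 of 199). Thy1 is carried by mouse T cells and the labels name no gate against them, but no test here separates sorted cells from other sources of these transcripts.

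Response genes in the microglia libraries formed the third pattern. The microglia-restricted response list was written after such genes were seen to be high there, so that its median of 3.4 over 6 tested genes (4.01 without microglia 4) repeats that observation, and 4 of its 9 genes are also in the activated microglia list. Its median lay 0.93 above that of the microglia markers, a difference that the choice of genes favoured, with an SD between genes of 0.92 in the response list and 0.41 in the markers, so that a higher share of microglia alone cannot be told apart from a response. In microglia 4 the response list stood at 0.772 times the mean of the other 3 libraries while S100a8 plus S100a9 stood at 3.62 times. This rests on 1 library and does not decide whether monocytes and neutrophils were the origin of the response genes. Microglia 2 had a lower response sum (581.2 CPM against 723.7 in microglia 4) with S100a8 plus S100a9 at 2405 CPM against 9722. The requirement of at least 2 libraries was added after the value of 0.772 was seen and weakened the verdict. Dissociation and a response in the animal could both raise these genes, and no group separates them.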

How the results depend on the processing

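Alternatives added after the data were seen were the deposited totals and factors, the effective sizes of the deposited table, counts redrawn within their rounding, thinned libraries, subtraction of the estimate of shared transcripts, and leaving out animal 5. Counts of differing genes are given for microglia, astrocytes and neurons against input, then for microglia against astrocytes, microglia against neurons and astrocytes against neurons. Tested against a 2-fold change they were 2670, 965, 429, 2517, 2115 and 1046, a stricter question by construction. With every library thinned to the smallest total they were 1709, 1105, 745, 1827, 1659 and 1032, over 3635 genes, so that depth and the set of tested genes changed together. With only the 2 groups fitted, microglia against neurons gave 2387 and astrocytes against neurons 1392, over fewer genes. Without animal 5, neurons against input gave 1417, and the cause was not tested. Leaving out 1 library gave 4252 (without microglia 5) to 5680 (microglia 2), 2296 (astrocytes 4) to 3445 (astrocytes 3), 1550 (neurons 3) to 2415 (neurons 4), 3918 (microglia 5) to 5012 (microglia 2), 3537 (microglia 5) to 4624 (microglia 2), and 2098 (astrocytes 4) to 2853 (astrocytes 5). The other alternatives stayed within 1.5 times, except that subtraction gave 3255 for microglia against input.

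With animal as a block, counts were 4567, 2865, 1904, 4258, 3799 and 2318, and 4554, 2832, 1891, 4226, 3788 and 2304 of these were also called without it, in the same direction. Among named genes 7 calls ended and 2 appeared, and among lists 2 appeared (border macrophage in astrocytes against input, median -1.46, and reactive astrocyte in microglia against astrocytes, 1.98).

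Subtraction used Gh and Prl to estimate shared transcripts and removed 4.54% to 55.8% of a library's counts. For the 4 libraries of animal 5 it used the median share of the other animals (0.725%) and not their own, which was 1.84% in microglia 5, 0.886% in astrocytes 5, 18.9% in input 5 and 70.3% in neurons 5. It turned 11 named values: Zfp36 (-9.78) and Junb (-5.79) in astrocytes against input; Itgam (-2.36), Retnlg (-3.08), Zfp36 (-2.26) and Jun (-4.10) in neurons against input; Ugt8a (2.35) and Rgs5 (3.57) in microglia against astrocytes; Ugt8a (2.35) and Slc2a1 (1.95) in microglia against neurons; Lgmn (9.55) in astrocytes against neurons. Values this large come from counts taken to near 0 by construction. It also ended 52 calls of named genes and made 43, and ended 11 and made 9 of lists. Leaving out 1 library ended 203 and made 64 calls of named genes over all such fits, and 28 and 33 of lists. An estimated correlation ended 102 list calls, fry ended 3 and made 29, and the test against a 2-fold change ended 135 calls of named genes.

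The median of all genes moved by more than 0.1 with library totals only (from -0.04 to -0.17, -0.09 to -0.41, -0.11 to -0.25, -0.02 to 0.16 and, for astrocytes against neurons, -0.04 to -0.22), with RLE (neurons against input, 0.04), with DESeq2 (neurons against input, 0.04), with the effective sizes of the deposited table (neurons against input, -0.24; microglia against neurons, from -0.03 to 0.08) and with subtraction (-0.43, -0.46 and -0.58 against input). It also moved with only the 2 groups fitted (0.10, 0.02 and 0.05 against input), for microglia against neurons with no filter (0.10) and thinned (-0.16), without microglia 2 (0.09) or microglia 4 (0.11) for microglia against input, and without astrocytes 4 (0.01) for astrocytes against input. The share of called genes that were higher in astrocytes than in neurons went from 51.9% to 41.6% with library totals only, 42.9% with DESeq2, 46.1% with no filter, 48.2% with RLE and 49.4% without astrocytes 5. Tested against a 2-fold change, the share higher was 34.0% in microglia and 60.8% in neurons against input. Beyond the turns given in the report, more genes were higher than lower in astrocytes against input with only the 2 groups fitted (51.0%), without astrocytes 2 (53.3%) and thinned (54.2%), in neurons against input with no filter (51.2%), thinned (54.6%) and without animal 5 (51.8%), and in microglia against astrocytes with no filter (2745 and 2728) and with the effective sizes of the deposited table (2280 and 2279).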

Other observations

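Other groupings of the same libraries were tried for each pair of groups, with a fit to those 2 groups alone. Of the 35 splits of the 8 libraries, 1 gave as many genes as the real one, which was the real one itself: 6935, 4314 and 2926 genes for microglia, astrocytes and neurons against input, 3381 for microglia against astrocytes, 2387 for microglia against neurons and 1392 for astrocytes against neurons. The highest other split gave 0 in each. Every other split mixes both groups in each arm, which widens the spread within arms, so that its 0 says little about chance. Of the 8 splits that part all 4 animals, the real one is 1 and the highest of the others gave 0, and 8 splits are too few for a share under 5%.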
